A study of Arabidopsis thaliana with 12 samples.

How the data were processed

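The samples were 12 RNA-seq libraries of polyadenylated RNA from Arabidopsis thaliana seeds 1 day after imbibition, grouped by their titles into WT normal, atcyp18-1 normal, WT heat and atcyp18-1 heat, with 3 libraries each. Per the labels' protocols, cDNA was made from fragmented RNA with random hexamers and ligated to index adapters. A strand-specific step is not described, so reads of overlapping and antisense genes cannot be told apart here. HTSeq and DESeq are named in the submitters' processing notes. Their versions, the aligner, the splicing caller and the genome build are not given in the sources used here.

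The deposited expression table gave raw read counts, per the file headers, for 57939 transcripts of 23337 genes, 14956 of them assembled transcripts without an annotated number. No count was 0, the lowest was 1, and 54256 cells held 1, so each value appears to be the read count plus 1. The transcripts of a gene had near-equal counts (median ratio of the lowest to the highest 0.990), so 1 transcript per gene was used, the lowest-numbered annotated one for 23315 genes and an assembled one for 22. The deposited normalized signal values were the raw counts divided by 1 factor per library, and the deposited log2 fold changes were those between group means of these values; both were checked against the counts and not used further. The authors' deposited splicing tables gave read counts on the junctions of 3 event types, and for intron retention the authors gave a scaled signal of intron reads and the ratio of intron reads to the mean reads of the adjacent exons. Each deposited event carried an unsigned ratio of group means and an unadjusted p-value per the file headers. The lowest ratio of a called event was 1.70 and the highest p was 0.0500. Both columns were recomputed from the deposited values for every called event, p within 0.001 and the ratio within 0.01. The p-values came from a test of 3 libraries against 3 that treats the junction reads as they are, unscaled to the gene's level or to library depth.

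Gene symbols and coordinates came from the reference annotation of TAIR10.1, which 23127 of the genes matched. Intron coordinates are those of the authors' deposited tables, and 98.9 to 99.3% of the introns began with GT and ended with AG in that reference.

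Genes were tested with edgeR 4.0.16 (R 4.3.3; TMM scaling, filterByExpr, quasi-likelihood F test) on the deposited counts, in 1 model of 4 group means over the 12 libraries, with the 4 pairwise comparisons and the interaction of heat and genotype. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Of the genes, 17296 passed the filter on low counts. CPM values are TMM-scaled. For a named or listed gene with at most 3 reads (count minus 1) over a compared group, the fitted fold change is not given; a ratio of TMM-scaled reads is given with an exact interval covering counting error, or, at 0 reads, a bound against a floor of 3 reads over the group. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, in limma 3.58.1 on log2 CPM with a prior count of 2, adjusted over 18 lists and 5 contrasts (90 tests). The preset test made 47 calls. With an estimated correlation it made 0 (17 at an unadjusted p under 0.05, lowest adjusted p 0.263), and fry made 53. Calls by camera that fry missed were photosynthesis in WT heat (adjusted p = 0.0806 by fry), the HSP70, HSP90 and HSP100 list (0.211) and small heat shock proteins (0.0819) in the unheated mutant, small heat shock proteins in the heated mutant (0.0593), and gibberellin (0.0542), photosynthesis (0.569) and seed storage genes (0.359) for the interaction. The 17 fixed lists held 319 genes, and 4 genes whose symbols did not match the reference were left out: PRP18B, U2AF65B, GEMIN2 and CYP65. The lists covered heat shock factors and heat-responsive regulators, HSP70, HSP90 and HSP100 chaperones, small heat shock proteins, ER protein folding, SR splicing factors, other spliceosome components, cyclophilins other than the mutated gene, seed storage proteins and oleosins, LEA genes, abscisic acid (ABA), gibberellin, cell wall loosening, storage lipid mobilisation, photosynthesis, oxidative stress, endosperm and seed coat markers, and root meristem and embryo axis markers. Cytosolic ribosomal proteins, 304 measured of 319 found by their description, made the other list.

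The genes named were fixed by a rule before the data were examined: CYP18-1; the 5 largest rises and 5 largest falls per contrast among called genes with a mean of at least 5 CPM in the higher group and, for the pairwise comparisons, groups that did not overlap; and per comparison up to 3 members of the 6 lists with the smallest camera p. The ribosomal list, found by description, was not counted among these 6. For splicing, the event with the smallest p of each type and up to 5 events in the splicing and heat shock lists were named. Genes outside the rule are marked in the text as chosen after their values were seen.

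Splicing events were tested with a quasi-binomial model per event on the 6 libraries compared, for events with at least 10 reads in every library, including junction events that the authors had not called, adjusted within each deposited table. Intron reads were set against exon reads. The intron tables gave no exon reads, so these were derived from the intron reads and the authors' ratio. The results read that ratio as a percentage. The model took it as a plain ratio, so its exon reads were too low if the ratio is a percentage. The read minimum, the adjusted p and the counts of introns passing depend on this scale, which is uncertain. The fixed design foresaw inclusion against exclusion reads, but the junction tables held no such pair, so junction reads were set against the remaining reads of the gene, a departure from that design made after the tables were seen. Directions were tested with exact binomial tests and overlaps with Fisher's exact test over 15093 tested genes with more than 1 exon. Events of a gene are not independent, nor are events read in the same libraries. Values of a single measure were compared with exact two-sided permutation tests, where 3 against 3 cannot give a p below 0.1.

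Depth was 7.48 M to 10.5 M reads per library. With 200 genes changed in simulated counts, edgeR recovered 47.1, 80.3 and 95.5% of changes of 0.5, 1 and 2 on the log2 scale for heat in WT, 41.2, 77.3 and 97.0% for heat in the mutant, 45.6, 80.3 and 98.5% for the genotypes without heat, 39.7, 78.8 and 97.0% for the genotypes in heat and 14.7, 57.6 and 89.4% for the interaction. The splicing model, tested on 2000 simulated events, recovered 25.0 and 65.0% of changes of 1 and 2 in log2 odds, with 5 false calls. Libraries of a group differed by more than sampling noise (chi-square per degree of freedom 2.29 to 8.14), so none was counted as a copy of another.

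The alternatives fixed before the data were examined were DESeq2 1.42.0, another scaling, no or another filter on low counts, a 2-fold minimum, a replicate block, leaving out each library, fitting only the compared libraries, stricter p and ratio thresholds and 1 event per gene for splicing, and 20 reads in place of 10. Chosen after seeing the data were counts minus 1, the transcript with the highest mean, leaving out organelle genes, AT2G07 genes, RR3 and 3 other nuclear genes, and plain library sizes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.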

Results

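The series measured polyadenylated RNA in germinating Arabidopsis thaliana seeds of the wild type (WT) and of atcyp18-1, a mutant of the cyclophilin gene CYP18-1. Cyclophilins are peptidyl-prolyl isomerases, enzymes that help proteins fold. Seeds were sampled 1 day after imbibition, either kept at the normal temperature or heated to 45 °C for 2 h. Each of the 4 groups had 3 libraries, 12 in all. The series addressed splicing and expression under heat in the mutant compared with the WT. The gene-level totals ran from 7.48 M to 10.5 M reads per library (M, mega-reads). Their mean was 9.16 ± 1.03 M in WT normal, 9.17 ± 0.795 M in mutant normal, 9.39 ± 1.09 M in WT heat and 8.32 ± 1.34 M in mutant heat (SD, n = 3 each). No label states that the libraries of a group came from separate plants or batches of seeds, so the p-values measure the spread between these samples, which may be technical.

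The mutated gene CYP18-1 (AT1G01940, chromosome 1, 322886 to 324917 in the TAIR10.1 annotation) was read at 22 ± 0.995 CPM (counts scaled to library size) in WT normal libraries and 1.93 ± 0.414 CPM in mutant normal libraries (SD, n = 3 each), 8.75% of the WT level. In heat the mean was 25.6 ± 0.548 CPM in WT and 3.37 ± 1.04 CPM in the mutant (SD, n = 3 each), 13.2% of the WT level. The genotypes did not overlap in either condition, and an exact two-sided permutation test gave p = 0.1 for each, the smallest value that 3 libraries against 3 allow. In edgeR's model the gene differed by -3.51 ± 0.17 (SE, log2) at the normal temperature (adjusted p = 2.35e-11) and by -2.91 ± 0.16 in heat (adjusted p = 3.17e-10). Each of the 6 mutant libraries lay below each of the 6 WT libraries. In the mutant the remaining reads rose by 0.82 ± 0.25 in heat (adjusted p = 0.00986), while the WT change of 0.22 ± 0.12 did not pass (adjusted p = 0.126), and the difference between these changes did not pass either (0.60 ± 0.27, adjusted p = 0.278).

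**Figure D1:**
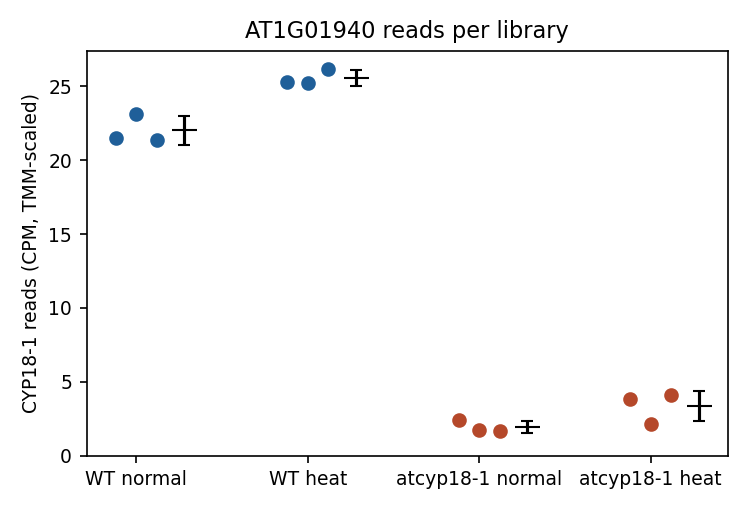
Reads of CYP18-1 (AT1G01940) in each of the 12 libraries, in TMM-scaled CPM on a linear axis starting at 0, by group; points are libraries, and the bar beside them is the mean ± SD of 3 libraries. The mutant means were 1.93 (normal) and 3.37 (heat), against 22 and 25.6 in WT.

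Of the 5 largest rises by heat in WT seeds, ranked by fitted log2 change, 3 were of heat shock genes. The order is uncertain for genes with few reads in WT normal. HSP17.6A-CI (AT1G59860, a cytosolic small heat shock protein) went from 1.45 ± 0.180 to 314 ± 83.8 CPM, and HSFA2 (AT2G26150), a transcription factor of the heat response, from 2.03 ± 0.504 to 347 ± 90.0 CPM (SD, n = 3 each). These are log2 changes of 7.75 ± 0.25 and 7.43 ± 0.24 (SE; adjusted p = 6.87e-16 and 4.93e-16). HSFA7A rose by 6.58. The others were the WD40 repeat gene AT2G05720, with 1 read in WT normal and 492 in WT heat, and AT1G30060, annotated as COP1-interacting protein-like, with 2 and 392. Their ratios were 555 (95% counting interval 99.2 to 21970) and 221 (60.8 to 1832). The 5 largest falls were all of plastid-encoded genes, namely RPS16 (-4.00), ORF77.2 (-3.87), ORF77.1 (-3.84), YCF2.2 (-3.69) and YCF2.1 (-3.69). The ORF77 and YCF2 genes each have 2 copies in the plastid's inverted repeat, so the split of reads between copies is uncertain. Plastid-encoded genes together fell from 10.7% ± 0.319 of reads in WT normal to 4.79% ± 0.304 in WT heat (SD, n = 3 each), while mitochondrial genes went from 4.49% ± 0.119 to 7.18% ± 0.409 (exact two-sided permutation p = 0.1 each, the smallest possible). The libraries were of polyadenylated RNA, so organelle values here and below count only the organelle RNA that entered them. They need not follow the levels of organelle transcripts in the seeds.

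Among the gene lists fixed before the data were examined, all 16 measured small heat shock proteins rose in WT (16 as well adjusted over the list alone; median log2 change 3.64), among them HSP17.4-CIII (5.55 ± 0.24) and mitochondrial HSP23.6 (4.47 ± 0.23). The camera test of this list gave an adjusted p = 2.78e-12, and an adjusted p = 0.263 with an estimated correlation. Of the HSP70, HSP90 and HSP100 chaperones and co-chaperones, 20 of 20 rose (20 over the list alone; median 2.73, adjusted p = 3.05e-13; adjusted p = 0.263 with an estimated correlation). HOP3, a co-chaperone linking HSP70 and HSP90, rose by 5.43 ± 0.21, BAG6 by 5.41 ± 0.21 and HSP70-4 by 3.08 ± 0.17. Of 20 heat shock factors and heat-responsive regulators, 12 rose and 3 fell (12 and 4 adjusted over the list alone; median 0.60, adjusted p = 0.00175; adjusted p = 0.358 with an estimated correlation). The bridging factor MBF1C rose by 4.83 and DREB2A, a regulator of heat and drought genes, by 3.33, while HSFA1A (-0.43), HSFA1D (-0.46) and HSFC1 (-0.64) fell, the last 3 being chosen after their values were seen. Of the 16 oxidative stress genes 8 rose (9 adjusted over the list alone; median 0.42, adjusted p = 0.00139; adjusted p = 0.263 with an estimated correlation), with GOLS1, which starts raffinose synthesis, at 3.75 and GSTU19 at 1.23. APX2, a peroxidase that removes hydrogen peroxide, had 0 reads in WT normal and 230 in WT heat, at least 86.5-fold higher against a floor of 3 reads over the group; at this bound it stays above the median of the list, which does not move.

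Of the 20 measured genes of SR proteins, which help choose splice sites, 11 rose in WT heat (11 adjusted over the list alone; median 0.39, adjusted p = 0.000484; adjusted p = 0.263 with an estimated correlation), led by SR45A (2.07 ± 0.17), SR30 (1.29 ± 0.15) and SCL33 (0.75 ± 0.10). Genes of protein folding in the endoplasmic reticulum (ER) mostly fell: 13 of 16 fell, in both adjustments, including calreticulin CRT1A (-0.71) and the disulfide isomerase PDIL1-1 (-0.57). The exception was the DnaJ co-chaperone ERDJ3A, which rose by 4.05 ± 0.32. The median of this list was -0.44 and its mean -0.16 (adjusted p = 0.00521; adjusted p = 0.358 with an estimated correlation). Seed storage proteins and oleosins rose in 11 of 13 cases in both adjustments (median 0.71, adjusted p = 0.00539; adjusted p = 0.527 with an estimated correlation). Late embryogenesis abundant (LEA) and related genes rose in 11 of 15, and 1, COR47, fell (11 and 2 adjusted over the list alone; median 0.76, adjusted p = 0.00548; adjusted p = 0.363 with an estimated correlation). Nuclear photosynthesis genes rose in 12 of 25 (12 adjusted over the list alone; median 0.45, adjusted p = 0.00524; adjusted p = 0.601 with an estimated correlation). Cytosolic ribosomal proteins rose in 206 of 304 cases and fell in 27 (209 and 29 adjusted over the list alone; median 0.40, adjusted p = 1.03e-13; adjusted p = 0.272 with an estimated correlation).

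In total 8669 of 17296 tested genes changed in WT heat at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 4320 higher and 4349 lower. Of these, 1631 changed at least 2-fold. The WT heat and normal libraries did not overlap for 56.0% of the tested genes, against 10% by chance. The share of higher calls, 49.8%, was 27.5% when libraries were scaled by their plain size, which moved the median of all genes by -0.21 on the log2 scale, so the directions given here are relative to the typical gene.

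In atcyp18-1 seeds the 5 largest rises by heat, ranked by fitted log2 change, were of heat shock proteins, heat shock factors and co-chaperones. HSP17.6A-CI rose by 8.59 ± 0.26, from 1.23 ± 0.452 to 469 CPM, and HSFA7A by 7.83 ± 0.32, HSFA2 by 7.76 ± 0.24, the FKBP-type co-chaperone ROF2 by 7.58 ± 0.36 and BAG6 by 7.21 ± 0.23 (SE, log2). The highest adjusted p of these 5 was 2.69e-13. The largest falls were again mostly plastid-encoded: ORF77.2 (-4.30), ORF77.1 (-4.28), ATPF, a subunit of the plastid ATP synthase (-3.54), and RPS16 (-3.51), with the nuclear gene AT3G23122 at -3.58. Plastid-encoded genes fell from 10.1% ± 0.236 to 5.35% ± 0.203 of reads, and mitochondrial genes went from 5.69% ± 0.254 to 8.03% ± 0.360 (SD, n = 3 each; exact two-sided permutation p = 0.1 each, the smallest possible).

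All 16 small heat shock proteins rose in the mutant in both adjustments (median 6.0, adjusted p = 2.79e-15; adjusted p = 0.263 with an estimated correlation), with HSP17.4-CIII at 6.37 and HSP23.6 at 6.14. Of the 20 HSP70, HSP90 and HSP100 genes 19 rose (19 adjusted over the list alone; median 4.06, adjusted p = 1.05e-15; adjusted p = 0.263 with an estimated correlation), with HOP3 at 6.52 and HSP90.1 at 4.96. Heat shock factors rose in 10 of 20 cases, DREB2A by 3.50, and fell in 2, HSFA1D (-0.67) and HSFC1 (-1.24), in both adjustments (median 0.33, adjusted p = 0.000775; adjusted p = 0.358 with an estimated correlation). Of the oxidative stress genes 11 rose and 1, RBOHD, fell by 0.35 (11 and 1 adjusted over the list alone; median 0.38, adjusted p = 0.000443; adjusted p = 0.263 with an estimated correlation), GOLS1 reaching 4.99 and GSTU19 1.37. APX2 had 2 reads in mutant normal and 330 in mutant heat, a ratio of 213 (95% counting interval 58.6 to 1770). HSFA1D, HSFC1 and RBOHD were chosen after their values were seen. Photosynthesis genes rose in 19 of 25 cases (21 adjusted over the list alone; median 0.66, adjusted p = 9.29e-05; adjusted p = 0.465 with an estimated correlation), among them plastocyanin PETE2 (0.93) and the Rubisco small subunits RBCS1B (0.73) and RBCS3B (0.66), near-identical genes whose reads may be split unevenly. LEA genes rose in 10 of 15 cases (11 adjusted over the list alone; median 0.63, adjusted p = 0.00053; adjusted p = 0.358 with an estimated correlation), with ECP63 at 1.26, LEA4-5 at 0.94 and LEA7 at 0.73.

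SR genes rose in 10 of 20 cases in both adjustments (median 0.26, adjusted p = 0.00139; adjusted p = 0.272 with an estimated correlation). Cytosolic ribosomal proteins rose in 168 and fell in 40 of 304 (172 and 41 adjusted over the list alone; median 0.28, adjusted p = 6.26e-08; adjusted p = 0.358 with an estimated correlation). In the mutant 4 of 16 ER folding genes rose and 4 fell, and the list did not pass (adjusted p = 0.764); seed storage genes rose in 4 of 13 (3 adjusted over the list alone) and did not pass either (adjusted p = 0.212). Heat changed 8010 genes in the mutant, 3966 higher and 4044 lower, 1692 of them at least 2-fold. The groups did not overlap for 54.6% of the tested genes, against 10% by chance, and the share of higher calls was 49.5% with TMM and 22.8% with plain library sizes (median shift -0.23).

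The 2 heat responses had 6044 changed genes in common, of which 6013 moved in the same direction and 31 in opposite directions. The log2 changes correlated with r = 0.868 across the tested genes, which are not independent replicates. No library was shared between the 2 comparisons.

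In unheated atcyp18-1 seeds against WT, CRC, the storage globulin cruciferin 3, was higher by 1.81 ± 0.21 (SE, log2), from 725 ± 175 to 2546 ± 291 CPM, and LHCB1.1, a chlorophyll-binding antenna protein, by 1.82 ± 0.32 (adjusted p = 5.65e-06 and 0.000358). The largest rise was that of AT3G28899 (chromosome 3, 10902184 to 10902515), a gene of unknown function, by 3.47 ± 0.16, from 2.13 ± 0.182 to 23.8 ± 1.31 CPM, followed by AT4G01985 (2.00) and AT1G49500 (1.86). After CYP18-1 itself, the largest falls were those of the zinc finger gene PMZ (-2.07), the plastid ribosomal genes RPS3 (-1.76) and RPL22 (-1.61), and CIP1, a COP1-interacting protein (-1.60).

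Seed storage proteins and oleosins rose in 12 of 13 cases in the mutant (13 adjusted over the list alone; median 1.11, adjusted p = 2.34e-09; adjusted p = 0.290 with an estimated correlation), including OLEO4, a protein of oil bodies (1.35 ± 0.12), and the albumin SESA2 (1.2 ± 0.14). Photosynthesis genes rose in 14 of 25 (17 adjusted over the list alone; median 0.51, adjusted p = 3.71e-07; adjusted p = 0.363 with an estimated correlation), with LHCB1.5 at 1.66, LHCA1 at 1.48 and LHCB4.2 at 1.26. The LHCB1 genes are near-identical copies, so their single values are uncertain. LEA genes rose in 7 of 15 and fell in 2, in both adjustments (median 0.65, adjusted p = 0.00378; adjusted p = 0.358 with an estimated correlation), with LEA4-5 at 0.87 and XERO1 at 0.83 against COR47 at -0.57 and ERD10 at -0.83, the last chosen after its value was seen. SR genes rose in 8 of 20 in both adjustments (median 0.24, adjusted p = 0.00053; adjusted p = 0.263 with an estimated correlation), with RSZ21 at 0.61, RS2Z33 at 0.48 and SC35 at 0.40.

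Folding genes of the ER fell in 10 of 16 in both adjustments and 1, BZIP60, rose by 0.36 (median -0.37, adjusted p = 0.00053; adjusted p = 0.327 with an estimated correlation). SHEPHERD, the HSP90 of the ER, fell by 0.75, ERDJ3B by 1.17 and BIP2, an ER-resident HSP70, by 0.48. Some heat shock proteins were lower in unheated mutant seeds. Of 16 small heat shock proteins 4 fell in both adjustments (median -0.74, adjusted p = 0.000679; adjusted p = 0.463 with an estimated correlation), and these were HSP17.6II (-1.11, adjusted p = 0.00439), HSP17.4 (-1.0, adjusted p = 0.0258), HSP23.5 (-0.91, adjusted p = 0.0168) and HSP21 (-1.84, adjusted p = 0.0432). Of the 20 HSP70, HSP90 and HSP100 genes 6 fell and 1, HSP70-2, rose by 0.33 (9 and 1 adjusted over the list alone; median -0.28, adjusted p = 0.0276; adjusted p = 0.601 with an estimated correlation). HSP21, BZIP60 and HSP70-2 were chosen after their values were seen. The calls of HSP17.4 and HSP23.5 were lost under 4 and 3 of the 16 alternatives, with adjusted p of up to 0.103 and 0.101. Cytosolic ribosomal proteins rose in 91 and fell in 24 of 304 (100 and 33 adjusted over the list alone; adjusted p = 0.000443; adjusted p = 0.486 with an estimated correlation), but their median of 0.12 turned to -0.016 with plain library sizes.

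The genotypes differed in 4047 genes without heat, 1936 higher and 2111 lower in the mutant, of which 256 differed at least 2-fold. The libraries did not overlap for 40.1% of the tested genes, against 10% by chance. Without atcyp18-1 normal replicate 3 the count was 2454, more than 1.5 times lower. The share of higher calls was 47.8% with TMM and 18.3% with plain library sizes (median shift -0.14).

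In heated mutant seeds against WT, AT3G28899 was higher by 3.38 ± 0.21 (SE, log2), EDL3, an F-box gene, by 2.67 ± 0.41, AT1G27565 by 2.63 ± 0.32, CBF2, a regulator of cold-responsive genes, by 2.48 ± 0.35, and MIPS2, an enzyme of inositol synthesis, by 2.26 ± 0.24, from 27 ± 13.2 to 130 ± 43.9 CPM. EDL3 and CBF2 spread widely within the mutant, at 7.40 ± 4.16 and 8.05 ± 4.18 CPM (SD, n = 3 each). Beside CYP18-1, the largest falls were AT3G60760 (-2.05), PMZ (-1.88), plastid RPS3 (-1.66) and AT5G47330 (-1.63).

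Of the 20 HSP70, HSP90 and HSP100 genes 13 were higher in the heated mutant (16 adjusted over the list alone; median 0.61, adjusted p = 5.63e-07; adjusted p = 0.358 with an estimated correlation), with HSP70-5 at 1.21, BAG6 at 1.1 and the plastid chaperone CLPB3 at 1.07. Small heat shock proteins rose in 12 of 16 and 1, HSP15.4, fell by 0.37 (15 and 1 adjusted over the list alone; median 0.75, adjusted p = 3.99e-05; adjusted p = 0.363 with an estimated correlation), with HSP18.2 at 1.93, HSP22 at 1.59 and the plastid HSP21 at 1.4. Heat shock factors rose in 7 of 20 and 2, HSFA3 (-1.23) and DREB2C (-0.67), fell (8 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.759). HSP15.4, HSFA3 and DREB2C were chosen after their values were seen. Photosynthesis genes rose in 19 of 25 (24 adjusted over the list alone; median 0.72, adjusted p = 1.05e-12; adjusted p = 0.308 with an estimated correlation), with LHCB1.5 at 1.82, LHCA1 at 1.64 and LHCB4.2 at 1.18. Seed storage genes rose in 8 of 13 (10 adjusted over the list alone; median 0.79, adjusted p = 2.8e-06; adjusted p = 0.358 with an estimated correlation), with CRC at 1.49, SESA2 at 1.02 and OLEO4 at 0.91. LEA genes rose in 6 of 15 in both adjustments (median 0.33, adjusted p = 0.00014; adjusted p = 0.308 with an estimated correlation), with RD29B at 1.23, M17 at 0.83 and LEA4-5 at 0.69. SR genes rose in 9 of 20 (10 adjusted over the list alone; median 0.23, adjusted p = 0.000487; adjusted p = 0.263 with an estimated correlation), with SR45A at 0.82, RS2Z33 at 0.37 and RS41 at 0.28. RS41 lost its call under 2 of 16 alternatives and RS2Z33 under 1, with adjusted p of up to 0.316 and 0.0765. The ER list (3 rose, 1 fell; adjusted p = 0.529) and the cytosolic ribosomal proteins (21 rose and 45 fell, 25 and 47 adjusted over the list alone; adjusted p = 0.314) did not pass.

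In heat 2879 genes differed between the genotypes, 1413 higher and 1466 lower in the mutant, 343 at least 2-fold. The libraries did not overlap for 32.6% of the tested genes, against 10% by chance. The count fell to 1820 without WT heat replicate 2, 1763 without atcyp18-1 heat replicate 1 and 1688 without atcyp18-1 heat replicate 3. The share of higher calls was 49.1% with TMM and 14.1% with plain library sizes (median shift -0.16). Between the 2 conditions, 674 genes were higher and 727 lower in the mutant in both, where independent lists would share 158 and 179, and 35 were called in opposite directions. These 2 comparisons shared no libraries, and their log2 differences correlated with r = 0.477 across genes.

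The heat response itself differed between the genotypes in 187 genes by the interaction test, 109 with a higher and 78 with a lower log2 change in the mutant. The log2 change of HSP21 was higher in the mutant by 3.24 ± 0.67 (SE), that of the plastid gene RPL33 by 2.76 ± 0.36, and those of MIPS2, HSP70-5 and HSP17.4 by 1.92 ± 0.40, 1.89 ± 0.29 and 1.81 ± 0.37. RPL33 spread widely in unheated mutant libraries, at 111 ± 70 CPM (SD, n = 3). At the other end stood VFB1, an F-box gene (-1.53 ± 0.25), AT2G32210 (-1.42 ± 0.33), the zinc finger gene AT2G41835 (-1.33 ± 0.27), LOJ (-1.27 ± 0.30) and AT4G03292 (-1.21 ± 0.21). VFB1 went from 7.57 ± 0.567 to 8.07 ± 0.735 CPM in WT and from 9.95 ± 0.138 to 3.63 ± 1.07 CPM in the mutant (SD, n = 3 each). The adjusted p of these 10 genes ran from 0.00123 (RPL33) to 0.0469 (LOJ). Under alternative processing 7 of these calls were lost at least once: LOJ in 12 of 20 fits, AT2G32210 in 11, AT2G41835 in 6 and AT4G03292 in 2 of 20, HSP21 and MIPS2 in 8 and HSP17.4 in 7 of 21, with adjusted p of up to 0.128.

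Of the 20 HSP70, HSP90 and HSP100 genes 8 had a larger change in the mutant (17 larger and 1 smaller adjusted over the list alone; median difference 1.06, adjusted p = 1.7e-11; adjusted p = 0.272 with an estimated correlation). Of the 16 small heat shock proteins 5 did (13 adjusted over the list alone; median 1.5, adjusted p = 3.56e-12; adjusted p = 0.263 with an estimated correlation). The 5 were HSP21, HSP17.4, HSP23.6 (1.68), HSP17.6II (1.58) and HSP23.5 (1.4). Folding genes of the ER had a higher change in 4 of 16, BIP1 (0.80), BIP2 (0.58), SHEPHERD (0.60) and ERDJ3B (1.1), with 9 and 1 adjusted over the list alone (median 0.36, adjusted p = 9.77e-06; adjusted p = 0.263 with an estimated correlation). Cytosolic ribosomal proteins had a lower change in 9 of 304 (1 higher and 33 lower adjusted over the list alone; median -0.13, adjusted p = 7.16e-07; adjusted p = 0.363 with an estimated correlation). HSP23.6, HSP17.6II, HSP23.5 and the ER genes were chosen here after their values were seen. Of the 187 genes, 97 had the larger absolute heat change in the mutant, and 71 had heat changes of opposite sign in the 2 genotypes.

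The interaction count depended on the processing. It was 298 with DESeq2, of which 31.2% were higher in place of 58.3%, and 22 without a filter on low counts. Leaving out 1 library gave 35, 55 and 101 genes for WT normal replicates 1, 2 and 3, 57, 111 and 43 for those of mutant normal, 313, 38 and 124 for WT heat, and 29, 291 and 22 for mutant heat.

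**Figure D2:**
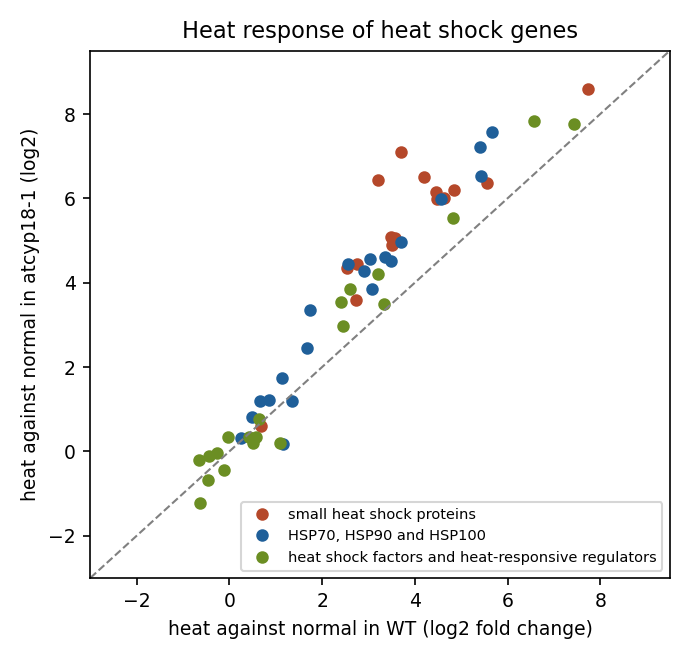
Log2 fold change by heat in WT (x axis) and in atcyp18-1 (y axis) for the measured members of the 3 heat shock lists, 1 point per gene from edgeR; the dashed line marks equal change. HSP21, HSP70-5 and HSP17.4 lie above the line by 3.24, 1.89 and 1.81.

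The authors' deposited tables listed more introns than events of any other type, and in heat mostly with more intron reads relative to exon reads. The types were called on unlike measures at unadjusted p-values, and the number of introns tested is not given. These counts therefore cannot rank the types or be set against chance. For heat, 2488 introns in 1259 genes were listed in WT and 2458 introns in 1291 genes in the mutant. Of these, 92.8% (95% exact interval 91.7 to 93.8) and 82.2% (80.7 to 83.7) had the higher ratio of intron to exon reads in heat. Between the genotypes the authors' deposited tables listed 282 introns in 258 genes at the normal temperature, 97.9% (95.4 to 99.2) of them higher in the mutant, and 310 introns in 254 genes in heat, 74.8% (69.6 to 79.6) higher. The intervals count each intron as independent, though all were read in the same libraries. They do not measure the spread between libraries. In WT heat, 71 introns in 17 genes of the HSP70, HSP90 and HSP100 list were listed, all higher, and 60 introns in 17 genes in mutant heat. The SR list held 18 introns in 6 genes in WT, all higher, and 26 introns in 8 genes in the mutant, 23 of them higher, while the other spliceosome genes held 12 (11 higher) and 9 (6 higher). The small heat shock proteins held 6 introns in 5 genes in each heat comparison. Cytosolic ribosomal protein genes, singled out after their values were seen, went the other way, with 14 of 78 introns higher in WT heat and 3 of 134 in mutant heat.

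**Figure D3:**
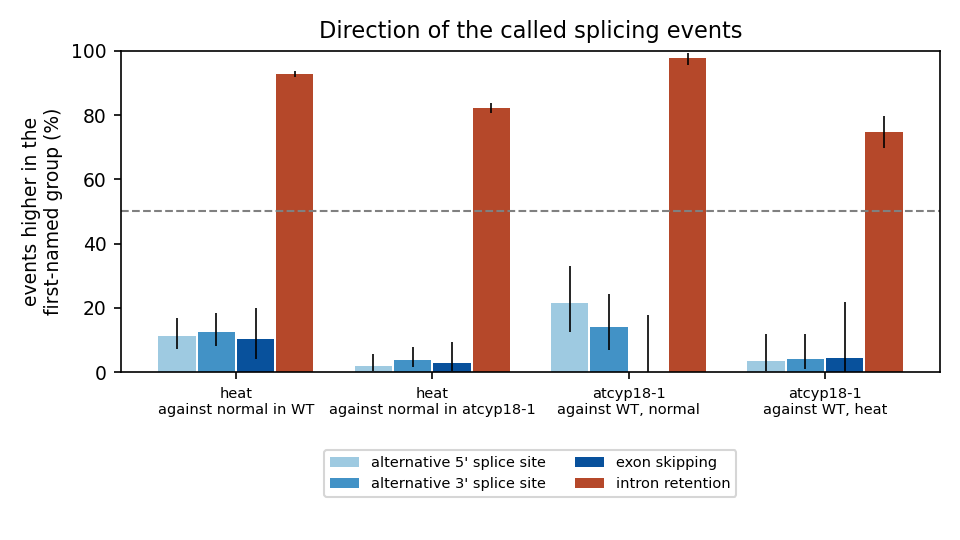
Share of the events in the authors' deposited tables with the higher value in the group named before "against" (y axis, percent, starting at 0), by comparison and event type; lines are 95% exact binomial intervals and the dashed line marks equal shares. Intron retention shares were 92.8, 82.2, 97.9 and 74.8%, and exon skipping in unheated mutant against WT was at 0%. The intervals count events as independent and do not measure the spread between libraries. Junction reads were not scaled to library depth.

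Many of these introns had a higher ratio in heat by large factors. In WT, intron 1 of HSP90.1 (chromosome 5, 21352680 to 21352994) went from 7.04 ± 3.42 to 123.4 ± 4.204 intron reads per 100 reads of the adjacent exons, and its intron 3 (21353503 to 21353590) from 1.19 ± 0.580 to 25 ± 0.860 (SD, n = 3 each). Intron 2 of HSP70-3 (chromosome 3, 2903062 to 2903145) went from 0.0588 ± 0.0192 to 1.59 ± 0.0277, the smallest p among introns in the authors' deposited table (6.67e-07, ratio 27.1). Intron 1 of HSP17.4-CIII (chromosome 1, 20179822 to 20179918) went from 2.50 ± 1.04 to 40.9 ± 1.36, and intron 7 of ROF2 from 11 ± 3.01 to 72.9 ± 3.19. In the mutant, intron 1 of HSFA7B (chromosome 3, 23399729 to 23400224) went from 3.15 ± 1.19 to 82.8 ± 1.19, introns 3 and 6 of ROF1 from 8.01 ± 1.26 to 62.9 ± 0.897 and from 4.86 ± 2.07 to 61.5 ± 2.30, intron 4 of HSA32 from 14.2 ± 2.45 to 56.6 ± 1.63, and intron 20 of PRP8, the core protein of the spliceosome, from 3.12 ± 0.686 to 14.8 ± 0.799. All of these with a quasi-binomial fit passed it, with adjusted p of 0.00118 for HSP70-3 and 0.00112 for HSFA7B, and ROF2 was not fitted. The authors had listed only introns selected on the same reads, so passing was near fixed beforehand and is no separate support.

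Between the genotypes the changes were smaller. In unheated seeds intron 6 of AT1G30580 (chromosome 1, 10833430 to 10833747) went from 2.50 ± 0.112 in WT to 4.34 ± 0.122 in the mutant. Also higher in the mutant were intron 4 of SCL30A (7.07 ± 0.910 to 12.3 ± 1.23), intron 10 of MAC3B (4.88 ± 1.63 to 10.6 ± 2.26), intron 5 of SCL33 (19.5 ± 4.84 to 33.6 ± 6.06) and intron 1 of RS40 (15.71 ± 3.54 to 29.4 ± 6.38), as was intron 3 of HSP70-3 (0.627 ± 0.167 to 1.11 ± 0.163). In heated seeds intron 9 of PRL1, a splicing-associated WD40 protein, went from 9.26 ± 5.97 to 28.9 ± 4.68 and intron 21 of PRP8 from 5.52 ± 1.07 to 9.54 ± 1.59, while intron 2 of the plastid gene PCLPP (plastid genome, 70945 to 71811) fell from 78.2 ± 3.41 to 28.8 ± 1.62. The adjusted p of these 9 introns in the quasi-binomial model ran from 0.00527 (PCLPP) to 0.0389 (SCL33 and RS40). They too had been selected on the same reads, so these values are no separate support.

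In that model 2418 of 2454 introns passed in WT heat, 2363 of 2419 in mutant heat, 272 of 281 for the genotypes without heat and 285 of 310 for the genotypes in heat. The introns had been selected by the authors on the same reads. The model took the authors' ratio as a plain one, while the results read it as a percentage. The model's exon reads were too low if that reading holds, and the intron counts in this paragraph depend on this. With the replicate block the counts of introns passing were lower in each comparison, most of all for the genotypes, as given in the part on processing. The genotype counts also rested on few libraries. Without WT normal replicates 1 and 2 in turn they were 175 and 176, and without mutant normal replicates 1, 2 and 3 they were 70, 117 and 134. In heat they were 73 and 117 without WT heat replicates 1 and 2, and 47, 134 and 0 without mutant heat replicates 1, 2 and 3. Of 1185 introns in both heat tables, the model called 0 with a different heat change in the 2 genotypes (90 at an unadjusted p under 0.05), and the median log2 change in odds was 1.85 in WT and 1.66 in the mutant. Introns listed for 1 genotype alone, which could differ most, were not tested. The 0 therefore does not show that heat acted alike on introns in both genotypes.

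Junction events went the other way. The authors' deposited tables listed 185 alternative 5' splice site, 183 alternative 3' splice site and 69 exon skipping events for heat in WT, of which 11.4, 12.6 and 10.1% had more junction reads in heat. For heat in the mutant they listed 157, 184 and 75, with 1.91, 3.80 and 2.67% higher. For the genotypes they listed 70, 71 and 19 events without heat (21.4, 14.1 and 0% higher in the mutant) and 58, 72 and 23 in heat (3.45, 4.17 and 4.35% higher). These junction reads were not divided by the gene's reads in the authors' deposited tables, and in 78.6 to 100% of the events, by comparison and type, the junction moved in the direction of its whole gene. Set against the remaining reads of the gene, 14, 21 and 3 of the listed events passed in WT heat, of 184, 181 and 69 tested. The same test passed 6, 10 and 3 in mutant heat (156, 182 and 74 tested), 5, 12 and 0 for the genotypes without heat (69, 70 and 19 tested) and 1, 3 and 0 for the genotypes in heat (57, 72 and 22 tested). With events that the authors had not called, the counts in WT heat were 15, 22 and 3 of 211, 200 and 76, and those of the other comparisons stayed the same. The exon skipping counts of 0 compare with 7 of 19 and 1 of 24 tested, called or not, at an unadjusted p under 0.05 in the quasi-binomial model, the only model run on these reads.

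The event with the smallest p of each type illustrates this. In WT heat the alternative 5' splice site junction of AT4G31210 (chromosome 4, 15166235 to 15166309) went from 81.7 ± 2.89 to 19 ± 2.65 reads (SD, n = 3 each) and passed against its gene's reads. The 3' splice site junction of FTSH12 (92.3 ± 6.35 to 32.7 ± 6.11) and the exon skipping junction of AT3G62360 (90.33 ± 7.37 to 30 ± 4.58) did not pass. In mutant heat ARA7 (down to 45.7 ± 6.43, listed as both a 5' and a 3' event) and IAA8 (156 ± 7.0 to 76 ± 7.0, exon skipping) did not pass. The same held for AT4G31230 (84.7 ± 7.23 to 36 ± 5.29), AT5G50565 (33 ± 1.0 to 17.7 ± 1.15) and PABN1 (55.3 ± 2.31 to 21.7 ± 1.53) in the unheated mutant against WT, and for AT5G22505 (104 ± 4.16 to 52.7 ± 1.53), RRP41L (45 ± 1.73 to 26 ± 2.0) and AT4G15640 (26 ± 2.65 to 12 ± 1.73) in heat. The adjusted p was 0.00206 for AT4G31210 and 0.056 or higher for the others, 0.056 being that of PABN1. For AT4G31230 and AT5G22505 the fitted log2 odds against the gene's remaining reads rose, by 2.44 and 2.58, opposite to the fall of their junction reads. Neither rise passed. Remaining reads were floored where junction reads exceeded the gene's count, so odds over few remaining reads are uncertain.

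Genes with a listed intron were more often among the genes changed in expression. Of 15093 tested genes with more than 1 exon, 867 had both in WT heat (621 expected; odds ratio 2.44, Fisher's exact adjusted p = 1.29e-47) and 865 in mutant heat (582 expected; 2.71, adjusted p = 5.35e-61). For the genotypes the overlap was 100 genes without heat (59.1 expected; 2.17, adjusted p = 1.14e-08) and 86 in heat (39.9 expected; 2.81, adjusted p = 1.60e-12). Among the genes in the upper part of the range of mean CPM, split at its median, the odds ratios were lower, at 1.54, 1.66, 1.37 and 1.90 (adjusted p = 1.44e-09, 1.37e-13, 0.0198 and 1.27e-05). Exon reads enter both the intron ratio and the gene's expression, so part of this overlap may be built in. The WT and mutant heat tables had 1203 introns in common, 1202 of them changed in the same direction, in 735 shared genes where independent lists would share 107. The tables of the genotypes, without and with heat, had 12 introns in common, 11 in the same direction, in 27 shared genes against 4.31 for independent lists. These expected numbers are over all 15093 genes. Genes with a listed intron lay mostly in the upper part of mean CPM, 1168 of 1258 in WT heat and 1202 of 1283 in mutant heat. Among such genes alone, independent lists would share more. Junction events shared between the heat tables, 52 at 5' sites, 63 at 3' sites and 23 skipped exons, all had the same direction, as did the 6, 13 and 1 shared between the genotype tables.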

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

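Of the tests in this part, the counts over other splits of the libraries and the test of scaling were chosen only after the result was seen.

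Heat responses differed between atcyp18-1 and WT in 187 genes by the interaction term of edgeR's model. Among 100 drawn splits of the libraries, of 200 distinct ones, 3 gave at least 187 genes, the real one included. The highest of the others called 2198 genes, several times the real count, and their median was 0. These splits are no reference for the interaction, since a split that exchanges genotypes in 1 condition turns the genotype difference, a structure of the samples, into the difference tested. The split with 2198 genes kept the genotypes apart without heat and took 1 WT library as WT in heat. Exchanging them in heat alone, a split that was not drawn, gave 5417 genes. Whether chance gives 187 genes was left undecided.

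The 10 genes singled out by the rule differed between the genotypes in their heat change by 3.24 (HSP21), 2.76 (RPL33), 1.92 (MIPS2), 1.89 (HSP70-5), 1.81 (HSP17.4), -1.53 (VFB1), -1.42 (AT2G32210), -1.33 (AT2G41835), -1.27 (LOJ) and -1.21 (AT4G03292) on the log2 scale. List medians that differed by the preset camera test were 1.5 for small heat shock proteins (adjusted p = 0.263 with an estimated correlation), 1.06 for HSP70, HSP90 and HSP100 genes (adjusted p = 0.272 with an estimated correlation), 0.36 for ER folding genes (adjusted p = 0.263 with an estimated correlation) and -0.13 for cytosolic ribosomal proteins (adjusted p = 0.363 with an estimated correlation). The others were 0.19 for photosynthesis genes (adjusted p = 0.0402; adjusted p = 0.689 with an estimated correlation), -0.24 for gibberellin genes (adjusted p = 0.0402; adjusted p = 0.358 with an estimated correlation) and -0.32 for seed storage genes (adjusted p = 0.0160; adjusted p = 0.577 with an estimated correlation). None of the photosynthesis and seed storage members passed by edgeR alone, nor did a gibberellin member until adjusted over the list alone, where 4 had the lower change.

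The larger rise of the heat shock protein genes in atcyp18-1 was weighed against both technical explanations that a table could test. The median difference over both lists of heat shock proteins lay 1.374 above that of all tested genes, and its lower quartile 0.792 above, which argues against scaling of the libraries, since a scaling factor moves all genes alike. Without each of the 12 libraries in turn the median stayed between 1.11 and 1.65, which argues against 1 library as its source. The difference held both lower levels in unheated mutant seeds (median -0.44) and higher levels in heated ones (0.72). An effect of the loss of CYP18-1 and a difference in the handling of the seeds between the groups were not tested and stay open, as the labels name no batch.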

How the results depend on the processing

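Of the alternatives in this part, counts minus 1, another transcript per gene, leaving out organelle genes with RR3, and plain library sizes were chosen only after the data were seen. Of 115 results of named genes, 104 kept their call in all alternatives, 11 lost it at least once, and none reversed. Over the 1872 fits of all 115 results, the call was lost in 64, all of them of these 11. For the interaction the call was lost in 12 of 20 fits for LOJ (adjusted p up to 0.128), 11 of 20 for AT2G32210 (0.128), 6 of 20 for AT2G41835, 8 of 21 for HSP21 and MIPS2, 7 of 21 for HSP17.4 (0.0975) and 2 of 20 for AT4G03292 (0.0538). The 2-fold minimum lowered the counts of changed genes, by construction, to 1631, 1692, 256, 343 and 41 for heat in WT, heat in the mutant, the genotypes without heat, the genotypes in heat and the interaction. The interaction count was 298 with DESeq2 (140 shared) and 22 without a filter on low counts, where more genes were tested. The cause was not tested elsewhere. Leaving out 1 library gave 22 to 313 genes for the interaction, 2454 to 3726 for the genotypes without heat and 1688 to 2698 in heat, with fewer samples by construction. The numbers in the titles were not taken to pair the libraries: deviations of same-numbered libraries correlated at -0.134 to 0.229, over 0.1 in 4 of 12 pairs. An effect shared by some same-numbered libraries is not excluded by these values. With the replicate block the interaction gave 324 genes, 187 of them shared, and the interaction of the heat shock factor list had an adjusted p = 0.0433. Estimated correlations lowered the list calls from 12, 11, 8, 9 and 7 to 0 in each contrast (17 of 90 tests at an unadjusted p under 0.05; fry made 53 calls).

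For the splicing tables, 5' sites, 3' sites, skipped exons and introns numbered 49, 60, 16 and 1005 for heat in WT at p under 0.01, 47, 48, 25 and 1035 for heat in the mutant, 11, 23, 8 and 79 for the genotypes without heat and 9, 16, 4 and 74 in heat. With a ratio of at least 2 the genotypes without heat kept 47 3' sites, 11 skipped exons and 135 introns, and in heat 35, 40, 15 and 148 of the 4 types. Counted as genes, retained introns numbered 1259 and 1291 for heat. At p under 0.01 the share of higher 5' sites in the unheated mutant was 27.3% (exact binomial p = 0.227) and that of skipped exons in the heated mutant 0% (p = 0.125). In the quasi-binomial model the replicate block, which leaves 2 residual degrees of freedom, gave 24 5' sites, 5 skipped exons and 1485 introns for heat in WT, 14, 19 3' sites and 1294 introns for heat in the mutant, 1 skipped exon and 9 introns for the genotypes without heat, and 3 5' sites, 16 3' sites and 28 introns in heat. Leaving out 1 library gave 6 to 9 5' sites, 6 to 24 3' sites and 0 to 5 skipped exons for heat in WT, and 1 to 5, 0 to 10 and 0 to 7 for heat in the mutant. For the genotypes it gave 1 to 4, 0 to 6 and 0 to 3 with 70 to 188 introns without heat, and 0 to 1, 0 to 4 and 0 to 1 with 0 to 205 introns in heat. The model recovered 25% of simulated changes of 1 in log2 odds.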

Other observations

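Of the tests in this part, the counts over other splits of the libraries and both tests of library depth were chosen only after the result was seen; those of intron reads and of words shared by RR3 were set before.

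Root meristem and embryo axis markers fell in 6 of 8 cases in WT (median -0.64, adjusted p = 0.0160; adjusted p = 0.263 with an estimated correlation) and in 5 of 8 in the mutant (6 adjusted over the list alone; median -0.62, adjusted p = 0.00378; adjusted p = 0.263 with an estimated correlation), with SCR, a regulator of the root's ground tissue, at -1.30 and -1.66. Without heat 1 marker, SHR, was higher in the mutant by 0.40, though not when adjusted over the list alone, and the list did not pass (adjusted p = 0.979), nor did it by camera in heat (adjusted p = 0.259), where fry called it as lower (adjusted p = 0.0192). Cell wall loosening genes fell in 6 of 14 and rose in 3 in WT heat (7 and 4 adjusted over the list alone; adjusted p = 0.312), fell in 7 and rose in 1 in mutant heat (8 and 1; adjusted p = 0.0598), and split 2 up and 3 down for the genotypes without heat (3 and 3; adjusted p = 0.657). In heated seeds 4 were lower in the mutant and 1 higher (median -0.20, adjusted p = 0.0393; adjusted p = 0.358 with an estimated correlation), with the expansins EXPA1 at -0.60 and EXPA10 at -0.57 and MAN7 at 0.43. Fry called the cell wall list as lower in both heat comparisons (adjusted p = 0.0208 in WT and 0.000399 in the mutant). Endosperm and seed coat markers, 4 measured, fell in 2 and rose in 1 in each heat comparison (adjusted p = 0.566 in WT and 0.208 in the mutant), with the mucilage gene MUM4 at -1.18 and -1.40. For the genotypes they gave an adjusted p = 0.900 without heat and 0.169 in heat, where MUM4 was lower by -0.49. These are camera values, while fry called this list as lower in both heat comparisons and for the genotypes in heat (adjusted p = 1.63e-05, 1.20e-06 and 4.32e-05).

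In the pairwise comparisons the ABA and gibberellin lists did not pass by camera, while fry called the gibberellin list in mutant heat (adjusted p = 0.0208). ABA genes, 20 measured, rose in 2 and fell in 5 in WT heat (adjusted p = 0.561), rose in 4 and fell in 2 in mutant heat (adjusted p = 0.849), rose in 4 and fell in 3 in the unheated mutant (adjusted p = 0.135) and rose in 6 and fell in 1 in the heated mutant (9 and 3 adjusted over the list alone; adjusted p = 0.0540). In the heated mutant NCED9, an enzyme of ABA synthesis, was higher by 1.48 and ABI4 lower by -0.49. Gibberellin genes, 18 measured, rose in 3 and fell in 4 in WT heat (adjusted p = 0.861), rose in 4 and fell in 7 in mutant heat (adjusted p = 0.314), rose in 5 and fell in 4 in the unheated mutant (adjusted p = 0.331) and rose in 2 and fell in 2 in the heated mutant (2 and 3 adjusted over the list alone; adjusted p = 0.301). GA3OX1 and GA3OX2, which make active gibberellin, rose by 0.71 and 0.89 in WT heat and by 0.80 and 0.81 in mutant heat. Storage lipid genes, 19 measured, rose in 8 and fell in 5 in WT heat (adjusted p = 0.133) and rose in 5 and fell in 1 in the unheated mutant (adjusted p = 0.212). They rose in 11 and fell in 5 in mutant heat (median 0.21, adjusted p = 0.0361; adjusted p = 0.274 with an estimated correlation), and 6 were higher in the heated mutant (8 adjusted over the list alone; median 0.13, adjusted p = 0.0026; adjusted p = 0.263 with an estimated correlation), though all 4 medians turned negative with plain library sizes. Where camera missed it, fry called this list as higher in WT heat (adjusted p = 5.62e-06) and in the unheated mutant (adjusted p = 0.00294).

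Other cyclophilins, 24 measured, rose in 10 and fell in 3 in WT heat (adjusted p = 0.0387; adjusted p = 0.263 with an estimated correlation) and rose in 12 in mutant heat (median 0.38, adjusted p = 0.00183; adjusted p = 0.263 with an estimated correlation). In the unheated mutant 5 were higher, CYP18-3 (0.48), CYP18-4 (0.43), CYP19-2 (0.44), CYP19-3 (0.24) and CYP28 (0.76), and CYP71 was lower (-0.39; adjusted p = 0.197 for the list by camera, 0.0192 by fry). In the heated mutant 5 were higher, CYP18-3 (0.37), CYP20-2 (0.37), CYP38 (0.40), CYP59 (0.47) and CYP95 (0.38; median 0.17, adjusted p = 0.00331; adjusted p = 0.263 with an estimated correlation). The other spliceosome genes, 27 measured, passed by camera in no pairwise comparison, while fry called them in WT heat (adjusted p = 0.0185): 8 rose and 10 fell in WT heat (adjusted p = 0.580), 9 and 10 in mutant heat (adjusted p = 0.908), 4 and 5 in the unheated mutant (5 and 5 adjusted over the list alone; adjusted p = 0.908) and 3 and 4 in the heated mutant (4 and 5; adjusted p = 0.425). Oxidative stress genes did not pass as a list for the genotypes (2 rose and 2 fell without heat, adjusted p = 0.655; 6 rose and 1 fell in heat, 7 and 2 adjusted over the list alone, adjusted p = 0.140), with AOX1A, the alternative oxidase, lower in the mutant by -0.59 and -0.99. Heat shock factors had 1 rise, HSFC1 (0.66), and 1 fall, HSFA1A (-0.62), in the unheated mutant (0 and 1 adjusted over the list alone by edgeR; adjusted p = 0.144). The genes named in these 3 paragraphs were chosen after their values were seen.

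The real split of each pairwise comparison gave more genes than the other 9 of its 10 splits, too few for a share under 0.05. The counts were 8669 against a highest other of 0 for heat in WT, 8010 against 0 for heat in the mutant, 4047 against 0 for the genotypes without heat and 2879 against 155 for the genotypes in heat.

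More introns were listed with a higher intron to exon ratio in heat than with a lower one. The intron reads of the listed introns themselves rose by a median of 1.08 (log2) in WT and 1.12 in the mutant, while exon reads changed by -0.29 and -0.03. For the listed introns this argues against falling exon reads alone as the source of the higher ratios. Because they had been listed for a changed ratio, the rise of their intron reads partly follows from that selection. Whether the intron background was fixed over all introns stays undecided. In WT the mean total of all reads in the heat libraries was 1.025 times that of the normal ones. However, the TMM factor of every WT heat library was lower than that of every WT normal library. The totals therefore do not give the depth over the typical gene and cannot decide on lower depth in WT, which stays open. In the mutant the ratio of mean totals was 0.907, a difference of 0.141 on the log2 scale. The lower quartile of the change of intron reads there was 0.4454. These reads were already scaled to library size, and the introns had been listed for a changed ratio. This value therefore cannot decide on depth in the mutant, which stays open. Slower or incomplete splicing in heat may account for the pattern and was not tested apart from RNA export, decay or residual genomic DNA.

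RR3 (AT2G41310), annotated as a response regulator, took 3.30% ± 0.207 of reads in WT normal, 5.15% ± 0.448 in mutant normal, 7.59% ± 1.05 in WT heat and 8.91% ± 0.646 in mutant heat (SD, n = 3 each). An exact two-sided permutation test gave p = 0.1, the smallest possible, for both heat comparisons and for the genotypes without heat, and 0.2 in heat. Of its 2951 words of 31 bases, 244 (8.27%) were found elsewhere in the genome, 0 of them in an organelle. This share lies between the values set for reads shared with other copies and against it, so that source cannot be told apart from transcription of the gene. RR3 and the organelle genes were left out in 1 of the alternatives for this reason.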
